A study of Mus musculus with 8 samples.

How the data were processed

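Poly(A) RNA sequencing was carried out on 8 libraries of mouse embryonic stem (ES) cells, 2 from each of 4 groups, and all 8 were used here. Per the labels, the groups were wild-type ES cells (mESC), the engineered ES cell line 2TS22C, and 2TS22C cells carrying a virus for SOX2 or for the SOX17 variant E57D and kept on doxycycline. Per the submitters' processing notes, reads were aligned to the mouse genome build mm10 with Bowtie2 2.0 and quantified with RSEM. The deposited table holds, for 15679 genes, a score per library that the submitters describe as normalised tag counts. The tool that made this normalisation was not given in the sources used here.

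The deposited score was checked against its own values before use. All values were whole numbers, the 8 libraries summed to between 15553884 and 15559217, and every library held the same number of distinct values, 1303, with the same highest value, 93197, shared by 10 genes. In mESC replicate 1, 145 of the 566 distinct values of at least 1000 were each shared by 10 genes, and 126 of these 145 had genes in at least 9 different classes when genes were put in 10 equal classes of GC content. This pattern is what a quantile normalisation within 10 classes of GC content would leave, and it was read from the values, not from a statement by the authors. The sequencing depth of each library is therefore not kept in the table, no counting interval can be given, and genes of different GC classes are not on one scale of reads. Genes were matched by Ensembl identifier to GENCODE M21, which held all 15679, and 14005 of them were protein-coding. Positions are on mm10.

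The values were treated as normalised expression and not as counts. They were put on the log2(value + 1) scale and fitted with limma 3.58.1 in R 4.3.3, with a trend of the prior variance on mean expression (limma-trend), one mean per group over all 8 libraries and no replicate block. The fit had 4 residual degrees of freedom and 2.12 prior degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, computed over the 15679 genes of a comparison. The filter, a value of at least 10 in at least 2 libraries, removed 0 genes, because every gene in the table reached 21 in at least 2 libraries. Fold changes are differences of group means on the log2(value + 1) scale, given with the SE from limma. With 2 libraries per group, exact permutation tests of single genes could not reach the threshold, so none was run. The labels do not say that replicates were separate cultures, so these p-values measure the spread between these libraries only.

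A total of 30 gene lists was fixed, and the 29 with at least 4 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 29 lists. Each list was also tested by camera with an estimated correlation and by fry, and its members were counted as past the test over all genes and adjusted over the list alone. The genes named were Sox2 and Sox17 in every comparison, and the 8 largest rises and 8 largest falls (5 and 5 in comparisons with mESC). These were ranked among called genes whose libraries did not overlap and whose higher group mean was at least 100. Predicted or unnamed genes, pseudogenes, and microRNA and small RNA genes were left out of the ranking. The largest rises and falls given below are those of this ranking. Per list, up to 4 called members with the smallest adjusted p were named, or up to 2 members with the largest fold change where none was called, and members of the general and naive pluripotency lists could all be named. Groups, comparisons, lists, tests, this rule and the first set of alternatives below were fixed before the data were examined. Any gene outside the rule is marked as chosen after its values were seen.

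The comparison of changes in SOX2 and E57D against 2TS22C shares its control libraries. Its agreement was set beside 100 simulated draws with no true difference and the same shared controls. The 2 control libraries were not split, as that would leave 1 for each comparison, so part of any excess may come from the shared controls. The procedure was tested on simulated data of 15679 genes per comparison. Known log2 changes of 1, 2 and 4 were put into 67, 67 and 66 of these genes, and the recovered shares are of those. At a log2 change of 1, 2 and 4, the test recovered 16.4%, 53.7% and 75.8% of the changed genes for E57D against SOX2. The recovered shares were 9%, 49.3% and 75.8% for SOX2 against 2TS22C and 16.4%, 50.7% and 77.3% for E57D against 2TS22C. They were 23.9%, 61.2% and 78.8% for 2TS22C against mESC, 23.9%, 50.7% and 77.3% for E57D against mESC, and 14.9%, 59.7% and 68.2% for SOX2 against mESC. Unchanged simulated genes were called 5, 6, 3, 5, 9 and 10 times in the same order, and 0 recovered genes had the wrong sign. The simulated groups all had the same spread per gene. In the real data, the SD of the log2 difference within a group ran from 0.097 (mESC) to 0.518 (2TS22C), over genes with a mean of at least 1000. The recovered shares and false calls therefore hold for equal spread only.

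The alternatives fixed beforehand were no filter, a value of at least 50 in 2 libraries, pseudocounts of 0.5 and 10, quantile normalisation, TMM scaling, limma without trend, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library of the compared groups. A fit with a library left out assumes that the remaining library of that group varies like the other groups. For lists, fry and the estimated correlation were added to these. Alternatives added after the data were seen were genes with a mean of at least 500, genes outside the lowest 3 GC classes, and leaving out the library labelled 2TS22C replicate 2 from comparisons that do not include it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.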

Results

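Gene expression was measured by poly(A) RNA sequencing in 8 libraries of mouse ES cells, 2 from each of 4 groups. Wild-type ES cells (mESC) came from another strain than 2TS22C, an engineered ES cell line whose Sox2 is switched off by doxycycline. In the other two groups, 2TS22C cells received a virus carrying either SOX2 or E57D, a form of the endoderm factor SOX17 with 1 amino acid exchanged, and were grown with doxycycline for 10 passages before analysis. The question behind the design is whether a changed SOX17 can stand in for SOX2 in keeping ES cells pluripotent. Values are normalised counts on one common total for all libraries, from 15553884 to 15559217, so the depth of each library is unknown. Fold changes are on the log2(value + 1) scale with their SE, and each compares 2 libraries with 2.

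Sox2, on chromosome 3 from 34650405 to 34652461, encodes a core pluripotency factor and had normalised counts of 4886 and 4825 in mESC and of 1170 and 1018 in SOX2 cells. It stood at 186 and 69 in E57D cells, and at 2612 and 4294 in the libraries labelled 2TS22C replicate 1 and replicate 2. Sox17, on chromosome 1 from 4490931 to 4497354, was listed at 0 in all mESC and 2TS22C libraries, at 2 in both SOX2 libraries, and at 441 and 92 in E57D replicates 1 and 2. Reads from the viral genes were counted at these mouse genes only as far as the sequences match, so viral and cellular transcripts cannot be separated.

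The library labelled 2TS22C replicate 2 resembled the mESC libraries and not its partner. Over 3587 genes with a mean of at least 1000, the SD of its log2 difference was 0.151 and 0.113 from the mESC libraries and 0.518 from 2TS22C replicate 1, while the mESC libraries differed from each other by 0.097. Hprt, a purine salvage enzyme on chromosome X from 52988137 to 53021659 chosen after its values were seen, stood at 5210 and 5454 in mESC, 1780 in 2TS22C replicate 1 and 5682 in the library labelled 2TS22C replicate 2. In the 4 transduced libraries Hprt lay between 390 and 452. Every comparison with 2TS22C below was therefore repeated without the library labelled 2TS22C replicate 2, and directions drawn against 2TS22C rest partly on it.

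**Figure D1:**
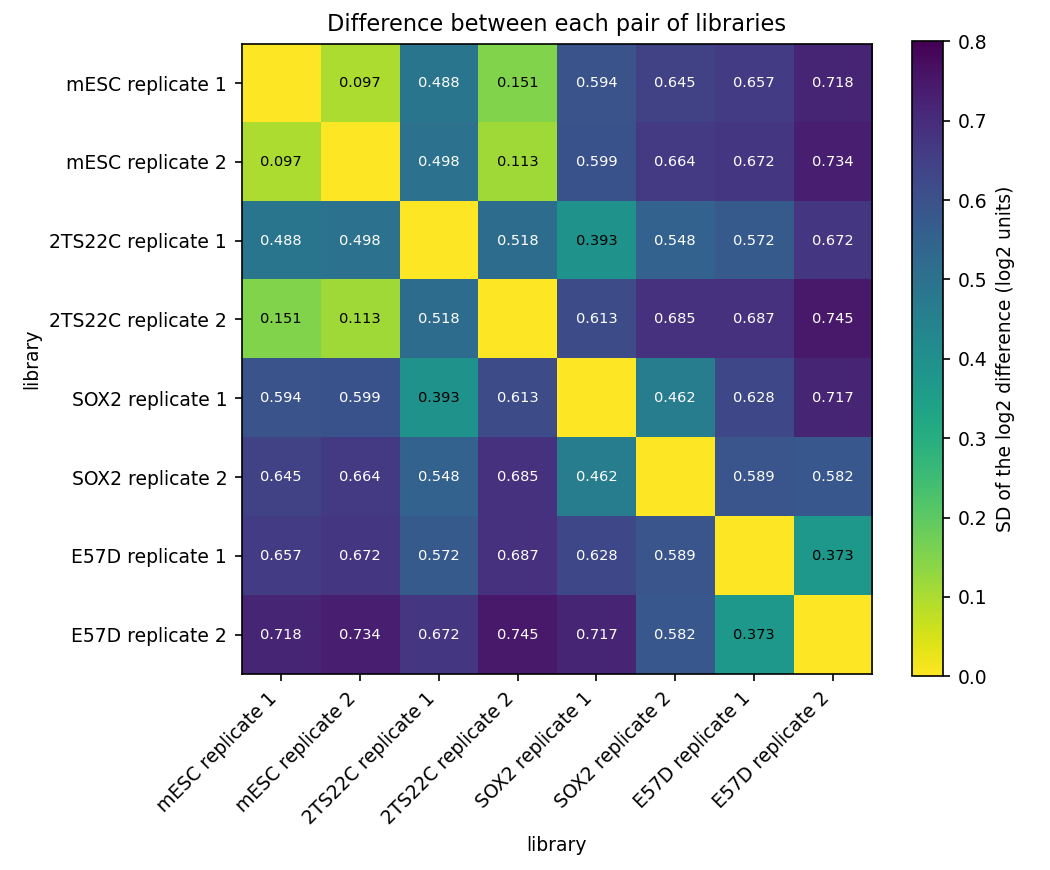
SD of the log2 difference between each pair of the 8 libraries, over 3587 genes with a mean normalised count of at least 1000, with libraries on both axes. The library labelled 2TS22C replicate 2 lies at 0.113 and 0.151 from the mESC libraries and at 0.518 from 2TS22C replicate 1.

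E57D cells were first compared with SOX2 cells, which differ by the labels only in the factor carried by the virus. Genes of primitive and extraembryonic endoderm rose in E57D cells, with 9 of 24 measured members past the test, 0 that fell and a median log2 fold change of 3.51. Gata6, a master regulator of primitive endoderm on chromosome 18 from 11052064 to 11085635, had 1696 and 1021 normalised counts in E57D and 34 and 42 in SOX2 cells, 33.9-fold higher (log2 fold change 5.09 ± 0.34, limma adjusted p = 0.00412). Pdgfra, a receptor used as a surface marker of primitive endoderm, was 30.3-fold higher (4.92 ± 0.46, adjusted p = 0.0102). Foxq1, a forkhead factor, stood at 910 and 434 in E57D and at 2 in both SOX2 libraries (adjusted p = 0.0123). Adjusted over the list alone, 17 endoderm genes rose and 1 fell, and the list as a whole was higher by camera (adjusted p = 1.73e-10, but adjusted p = 0.449 with an estimated correlation) and by fry (adjusted p = 0.00785).

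Trophoblast genes were also higher in E57D cells, with 3 of 16 past the test and a median log2 fold change of 0.83. Krt18 and Krt8, keratins of simple epithelia, rose 52.2-fold (5.71 ± 0.44, limma adjusted p = 0.00549) and 66.8-fold (6.06 ± 0.62, adjusted p = 0.0127), and Elf3, an epithelial transcription factor, rose by 2 on the log2 scale (adjusted p = 0.039). Krt8 and Krt18 are made by many epithelia, primitive endoderm included. The list passed by camera (adjusted p = 0.0113; adjusted p = 0.449 with an estimated correlation) and by fry (adjusted p = 0.0112), and 5 members rose adjusted over the list alone. The camera call ended without SOX2 replicate 1 (median 0.9, adjusted p = 0.0596), without SOX2 replicate 2 (median 1.3, adjusted p = 0.0823) and without E57D replicate 1 (median 0.23, adjusted p = 0.0961). Lists of definitive endoderm (9 measured), mesoderm (8 measured) and other Sox genes (9 measured) had 0 members past limma's test, with camera adjusted p of 0.764, 0.974 and 0.694. Definitive endoderm passed by fry (adjusted p = 0.0491), with 4 members higher and 2 lower adjusted over the list alone.

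**Figure D2:**
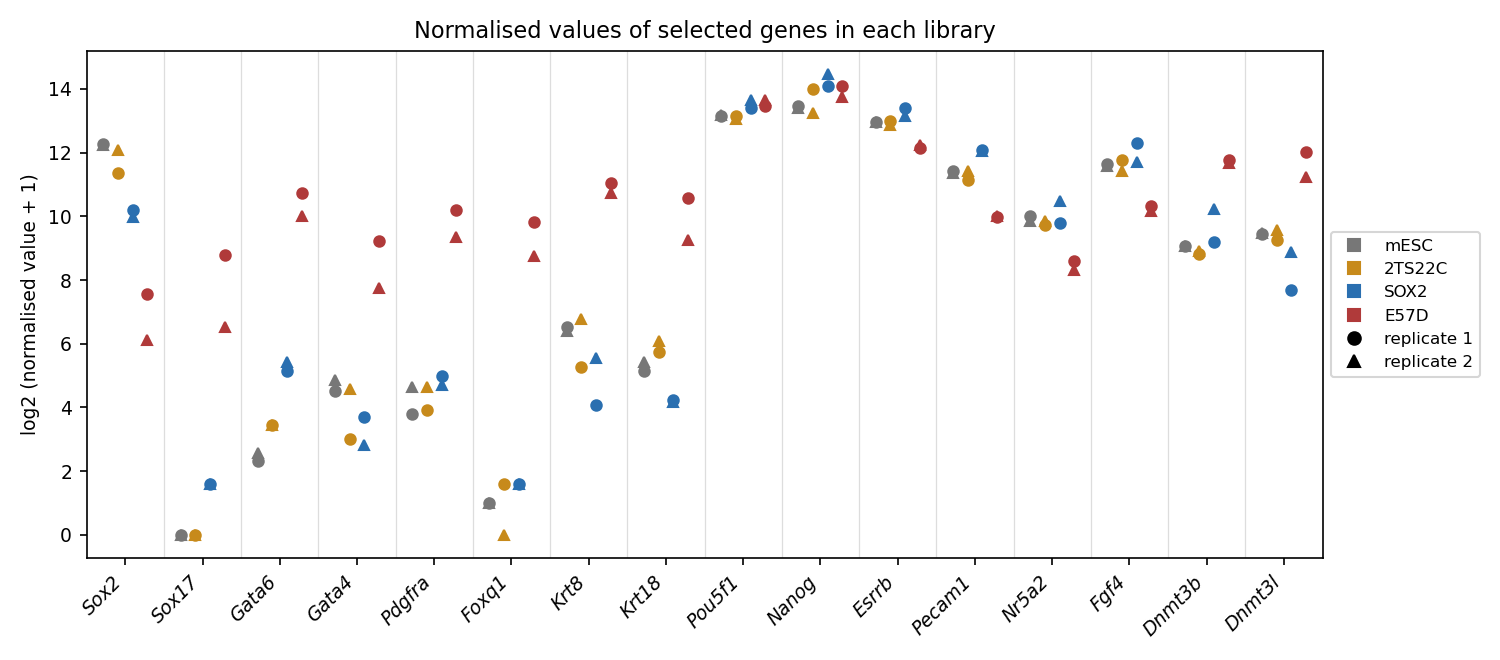
Normalised counts of selected genes in each of the 8 libraries on a log2(value + 1) axis. Each point is 1 library, coloured by group and shaped by replicate. Gata6 lies at 1696 and 1021 in E57D and at 42 or less in the other 6 libraries.

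General pluripotency genes did not move in one direction as a group, with 1 of 18 higher, 1 lower, a median log2 fold change of 0.16 and a camera adjusted p of 0.974. Adjusted over the list alone, 4 members were higher and 3 lower, so single members moved in both directions. Pou5f1, which encodes OCT4, was at 11274 and 12892 in E57D against 10784 and 12892 in SOX2 cells, a log2 fold change of 0.03 with a 95% interval from -0.26 to 0.32. The interval for Nanog was wider, from -1.02 to 0.3. Naive pluripotency genes were lower, with 3 of 20 past the test and a median of -0.67. Pecam1, a surface protein of naive ES cells, fell 4.2-fold from 4332 and 4244 to 1006 and 1036 (log2 fold change -2.07 ± 0.12, limma adjusted p = 0.00266). Esrrb, an orphan nuclear receptor of the naive network, fell 2.11-fold (-1.08 ± 0.12, adjusted p = 0.0138), and Nr5a2, another nuclear receptor, fell 3.21-fold (-1.68 ± 0.25, adjusted p = 0.0296). Klf4, Tbx3 and Zfp42, of the same list, had log2 fold changes of 0.26, -0.21 and -0.57 and did not pass. The naive list passed by camera (adjusted p = 0.00147; adjusted p = 0.77 with an estimated correlation) and by fry (adjusted p = 0.0491), with 6 members lower and 2 higher adjusted over the list alone, and its camera call ended without E57D replicate 1 (adjusted p = 0.0568).

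Fgf4, a growth factor gene regulated by OCT4 and SOX2, fell to 1286 and 1144 from 5033 and 3330 (-1.75 ± 0.22, limma adjusted p = 0.022), and Lefty1, an inhibitor of Nodal signalling, stood at 66 and 100 in E57D and at 2 and 0 in SOX2 cells (adjusted p = 0.0426). Neither call held in every fit with a compared library left out. Against 2TS22C without the library labelled 2TS22C replicate 2, Lefty1 was at log2 fold changes of -7.59 in SOX2 cells and -2.02 in E57D cells. The rise of Lefty1 over SOX2 cells thus went with near absence in SOX2 cells and did not exceed 2TS22C replicate 1. Among OCT4-SOX2 enhancer genes, 1 of 10 rose and 1 fell (camera adjusted p = 0.974). Dnmt3l and Dnmt3b, a cofactor and an enzyme of DNA methylation that mark formative cells, rose by 3.35 and 2.01 on the log2 scale (limma adjusted p = 0.0232 and 0.0359). They were the only 2 of 16 measured formative and primed genes past the test. The median of that list was -0.23 and its camera adjusted p 0.974. The same pair were the only 2 of 13 DNA methylation genes past the test.

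Cholesterol synthesis genes were higher in E57D cells, with 6 of 23 past the test, 15 adjusted over the list alone, and a median log2 fold change of 0.96. Hmgcs1, which encodes an early enzyme of the pathway, rose from 2553 and 2206 to 6052 and 5210 (1.24 ± 0.2, limma adjusted p = 0.0381), and Sc5d, which encodes a late enzyme, rose by 0.96 (adjusted p = 0.0415). Glycolysis and hypoxia genes were higher with 4 of 26 past the test and a median of 0.55. They included Bnip3, a hypoxia-induced mitophagy receptor (3.41 ± 0.4, adjusted p = 0.0175), Pfkl, a subunit of phosphofructokinase (2.21 ± 0.3, adjusted p = 0.025), and Pdk1, which restrains pyruvate entry into mitochondria (1.64 ± 0.26, adjusted p = 0.0346). Adjusted over the list alone, 13 glycolysis and hypoxia genes rose and 1 fell. Against 2TS22C the median of this list was -1.65 in SOX2 cells and -0.68 in E57D cells. The higher level in E57D than in SOX2 cells was thus a smaller fall from 2TS22C, not a rise above it. Camera gave adjusted p of 4.69e-08 for cholesterol and 0.00147 for glycolysis (adjusted p = 0.77 with an estimated correlation for both), and fry gave adjusted p of 0.0491 and 0.0609. Without SOX2 replicate 2 the camera adjusted p for glycolysis was 0.0542.

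Targets of p53 were lower by camera (adjusted p = 0.00147; adjusted p = 0.933 with an estimated correlation; median -0.47, or -0.19 without SOX2 replicate 1, adjusted p = 0.125) but not by fry (adjusted p = 0.294). Of these, 1 of 20 passed, Ei24, an endoplasmic reticulum protein involved in autophagy, at -1.11 (limma adjusted p = 0.0146). Of 14 LIF-STAT3 targets 3 fell, namely the kinase genes Pim3 and Pim1 and the signalling inhibitor Socs2, at log2 fold changes of -1.11, -1.66 and -2.39, with a camera adjusted p of 0.172 for the list. Ccnd1, a cyclin that drives entry into S phase and a member of both the WNT and cell cycle lists, fell 8.55-fold (adjusted p = 0.0146), the only member past the test of 11 and of 24. Ifitm3, an interferon-induced membrane protein that also marks early germ cells, fell 6.27-fold (adjusted p = 0.0049), the only member past the test of 13 interferon response genes (camera adjusted p = 0.974). In the extracellular matrix and adhesion list 4 of 23 rose and 1 fell, with Fn1, which encodes fibronectin, lower by 3.78-fold, and the fibroblast marker list had 2 rises and 1 fall among 16. Lgals1, which encodes the lectin galectin-1, rose from 70 and 53 to 1256 and 1674 (4.55 ± 0.34, adjusted p = 0.0049). Ncam1, a neural adhesion molecule, was the only neuroectoderm gene of 9 past the test and was lower at -3.5 (adjusted p = 0.0304). Grb10 and Sgce, imprinted genes, went in opposite directions, at -2.88 and 1.82, as the only 2 of 19 past the test. Among 25 germline genes, 1 rose (Brdt) and 1 fell (Dpep3), and 1 of 14 TGF-beta, Nodal and BMP targets rose and 1, Smad6, fell. ERK and FGF feedback genes, integrated stress response genes, endoplasmic reticulum chaperones, Polycomb genes, 2-cell-like genes and mitochondrial genome oxidative phosphorylation genes had 0 members past limma's test, with camera adjusted p of 0.974, 0.167, 0.694, 0.694, 0.694 and 0.773. Leaving out E57D replicate 2 added LIF-STAT3 targets on the lower side and extracellular matrix genes on the higher side by camera (adjusted p = 0.0395 and 0.017), and leaving out E57D replicate 1 added integrated stress response genes on the lower side (0.013). The sex-linked list had 3 measured genes, too few to test.

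Over all genes, limma called 489 changed between E57D and SOX2 cells, 241 higher and 248 lower, against 3560 at an unadjusted p under 0.05. Sox2 itself was 9.55-fold lower in E57D cells (-3.26 ± 0.47, adjusted p = 0.0285). The count was 191 without SOX2 replicate 1 (120 higher, 71 lower), 926 without SOX2 replicate 2 (495 and 431), 289 without E57D replicate 1 (78 and 211), 93 without E57D replicate 2 (42 and 51), and 734 when the library labelled 2TS22C replicate 2 was dropped from the shared estimate of spread (331 and 403). The balance of higher and lower genes therefore depends on single libraries. Of 55 named genes past the test, 10 passed with each of the 4 libraries left out in turn, among them Gata6, Pdgfra, Krt18, Lgals1, Pecam1 and Ifitm3, and Sox2 did not without E57D replicate 2 (adjusted p = 0.0548), SOX2 replicate 1 (0.108) or SOX2 replicate 2 (0.0515). The largest rises were in Mbd3l2 (368 and 451 in E57D), Tfec (280 and 224), Cldn1 (194 and 224) and Sptssb (134 and 104), all listed at 0 in both SOX2 libraries, Pth1r, which encodes a parathyroid hormone receptor (721 and 176 against 2 and 1), and the olfactory receptors Olfr881 and Olfr1054. The largest falls were in Fstl5, Tpte, Ssxb9, Olfr250 and Olfr1277, at 2 or less in E57D, and in Pianp (35 and 5 against 694 and 558), Kbtbd11 (6 and 1 against 166 and 118) and Cbln1 (16 and 4 against 268 and 414). Olfactory receptors belong to a large family of similar sequences, and values near 0 in some libraries and high in others were frequent in the lowest 3 of 10 equal classes of gene GC content. Those classes held 4704 of the 15679 genes tested and 18.2% of the called genes (89 of 489), a smaller share than of all genes. Among the 51 called genes at 2 or less in both libraries of one group, however, 30 lay in those classes, a larger share than of all genes.

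**Figure D3:**
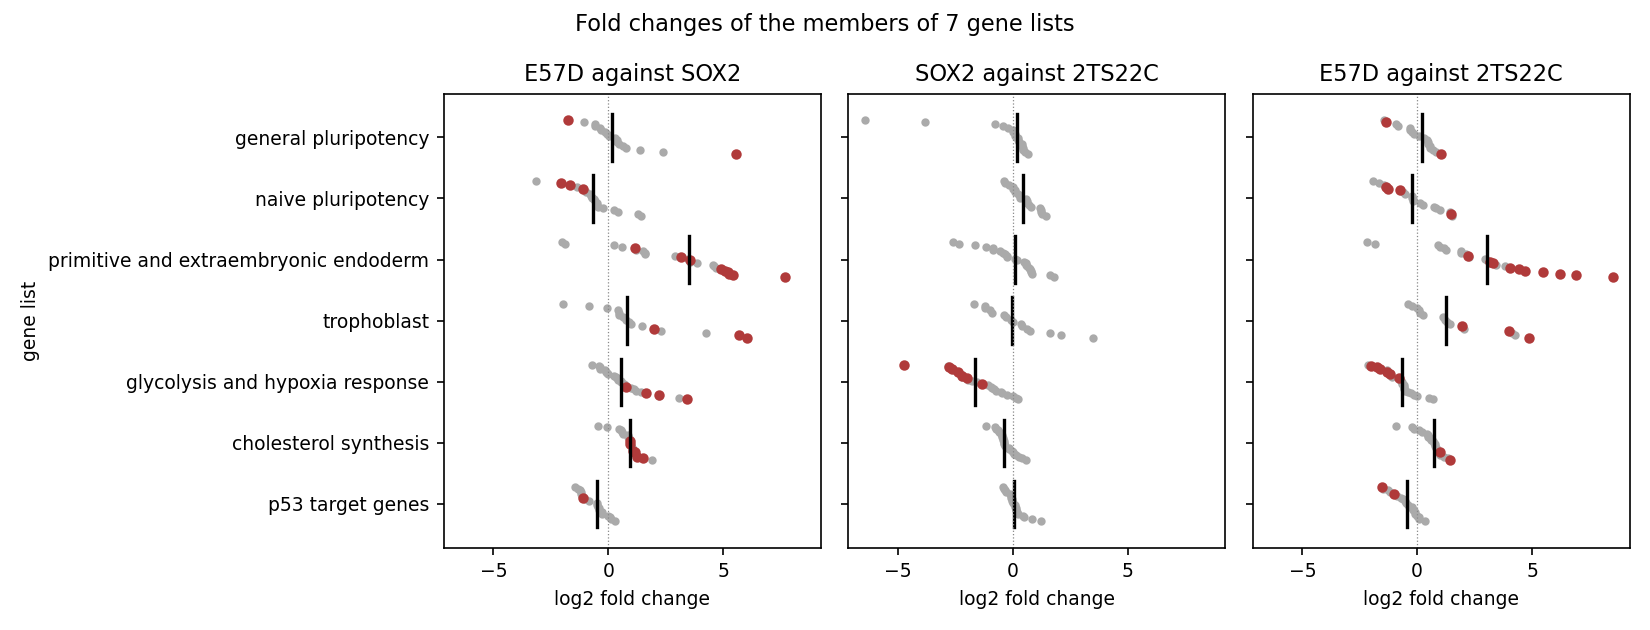
Log2 fold change of each measured member of selected fixed gene lists, with 1 point per gene, on a log2(value + 1) scale. The lists are general and naive pluripotency, endoderm, trophoblast, glycolysis and hypoxia, cholesterol synthesis and p53 targets. Points are red where the gene passed limma's test, and a black bar marks the list median. Between E57D and SOX2 cells the endoderm list has a median of 3.51 and the general pluripotency list a median of 0.16.

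SOX2 cells were compared with untreated 2TS22C cells, from which they differ in virus and doxycycline together. Glycolysis and hypoxia genes fell in SOX2 cells, with 7 of 26 past the test, 19 adjusted over the list alone, and a median log2 fold change of -1.65. Ldha, which encodes lactate dehydrogenase A, fell 6.84-fold, from 22736 and 34005 to 4244 and 3890 (-2.77 ± 0.19, limma adjusted p = 0.00928). Pgk1, which encodes phosphoglycerate kinase, fell 5.13-fold (adjusted p = 0.0169), Bnip3 fell 26.4-fold (adjusted p = 0.0169), and Pkm, which encodes pyruvate kinase, fell by 1.97 on the log2 scale (adjusted p = 0.00928). Aldoc, a glycolytic aldolase, fell from 1112 and 1228 to 81 and 70 (-3.94 ± 0.15, adjusted p = 0.00132). The list was lower by camera (adjusted p = 3.03e-16; adjusted p = 0.361 with an estimated correlation) and by fry (adjusted p = 0.00877). Without the library labelled 2TS22C replicate 2, the list kept a median of -1.76 (adjusted p = 9.62e-17), Ldha was at -2.48 (adjusted p = 0.0126) and Aldoc at -3.87 (adjusted p = 0.0126), whereas Pkm, Pgk1 and Bnip3 no longer passed (adjusted p = 0.053, 0.0631 and 0.101).

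Naive pluripotency genes were higher as a list in SOX2 cells than in 2TS22C by camera (median 0.47, adjusted p = 0.00102; adjusted p = 0.579 with an estimated correlation), although 0 of 20 members passed limma's test over all genes, 4 rose adjusted over the list alone, and fry did not pass (adjusted p = 0.199). Klf4 and Tbx3 were at log2 fold changes of 1.23 and 1.19. The list stood at 0.33 without the library labelled 2TS22C replicate 2 (adjusted p = 0.0124). Mitochondrial genome oxidative phosphorylation genes were higher by camera (adjusted p = 0.0283; adjusted p = 0.52 with an estimated correlation) and by fry (adjusted p = 0.0494), with 1 of 13 past the test, the complex I gene mt-Nd4l (1.22 ± 0.13, adjusted p = 0.0314). The gene missed the test without the library labelled 2TS22C replicate 2 (0.0827) and without SOX2 replicate 2 (0.113), and all 13 genes of the list lie in the lowest 3 GC classes. Genes of 2-cell-like cells were higher by camera (adjusted p = 0.0335; adjusted p = 0.627 with an estimated correlation) but not by fry (adjusted p = 0.608), with 0 of 13 members past the test. The mitochondrial call ended without 2TS22C replicate 1 (adjusted p = 0.0678) and without SOX2 replicate 2 (0.135), and the 2-cell-like call without 2TS22C replicate 1 (0.0678), without SOX2 replicate 1 (0.652) and outside the lowest 3 GC classes (0.114) and with TMM scaling (0.0556). The mitochondrial and 2-cell-like lists were at adjusted p of 0.0264 and 0.0124 without the library labelled 2TS22C replicate 2. The cell cycle list passed by fry (adjusted p = 0.00877) and not by camera (0.0582). Sox2 was at -1.62 ± 0.47 (adjusted p = 0.275), and at -1.26 without that library (adjusted p = 0.555), and Pou5f1 and Nanog were at 0.43 and 0.67 (adjusted p = 0.26 and 0.386).

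In this comparison limma called 44 genes, 19 higher and 25 lower, against 1998 at an unadjusted p under 0.05, and 39 without the library labelled 2TS22C replicate 2 (22 and 17), of which 19 were among the 44. The split was 9 higher and 31 lower without SOX2 replicate 2, 5 and 19 outside the lowest 3 GC classes, and 3 and 16 among genes with a mean of at least 500, the last 2 settings chosen after the data were seen. Lists past camera went from 4 to 12 without that library, as mesoderm and integrated stress response genes were added on the higher side (adjusted p = 0.00982 and 0.0437) and formative, neuroectoderm, other Sox, imprinted, TGF-beta and cell cycle genes on the lower side (0.0264, 0.0478, 0.0312, 0.0178, 0.0178 and 0.0432). Leaving out 2TS22C replicate 1 added endoderm, LIF-STAT3 and p53 genes on the higher side (0.0482 each) and endoplasmic reticulum chaperones and cholesterol synthesis genes on the lower (0.000605 and 0.000816). Polycomb genes were added on the higher side without SOX2 replicate 1 (0.0469), and without SOX2 replicate 2 germline, p53 and fibroblast genes on the higher (0.0113, 0.00182 and 0.0154) and cholesterol genes on the lower (0.0268). Limma called 243 without 2TS22C replicate 1 (175 higher, 68 lower) and 158 without SOX2 replicate 1 (47 and 111), and 47.7% of the 44 genes lay in the lowest 3 GC classes. Of 19 named genes past the test, 7 passed with each of the 4 libraries left out, among them Ldha, Aldoc and Trh. Trh, which encodes thyrotropin-releasing hormone, fell by 5.73 on the log2 scale (adjusted p = 0.00928), and Anxa2, a membrane-binding annexin, fell by 3.86 (adjusted p = 0.0333, or 0.149 without the library labelled 2TS22C replicate 2). Other named falls were Cldn1, Olfr698 and Olfr1265, listed at 0 in both SOX2 libraries, and Ftl1, which encodes the ferritin light chain (-6.27 ± 0.62, adjusted p = 0.025). Ftl1 is uncertain because its near-identical copy Ftl1-ps1, chosen after its values were seen, was at 32 to 38 wherever Ftl1 was at 93197 and at 27115 or more elsewhere. Named rises were Ubtfl1, Ssxb9, Tmprss11e, Syde1, Caskin1, Tnfrsf21, Rplp0 and mt-Nd4l. The ribosomal stalk gene Rplp0 was at 1.25 ± 0.13 (limma adjusted p = 0.0327). In a fit of only the SOX2 and 2TS22C groups limma called 0 genes, so no call of this comparison held there. Ssxb9, Syde1, Caskin1, Tnfrsf21 and mt-Nd4l missed the test without the library labelled 2TS22C replicate 2 (0.0555, 0.101, 0.0658, 0.147 and 0.0827), and Rplp0 missed it without SOX2 replicate 1 (0.0619) and without SOX2 replicate 2 (0.13).

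E57D cells were compared with untreated 2TS22C cells, from which they differ in virus, factor and doxycycline together. Endoderm genes rose with 10 of 24 past the test, 19 up and 1 down adjusted over the list alone, and a median log2 fold change of 3.02. Gata6 rose by 6.9 ± 0.34 on the log2 scale (limma adjusted p = 0.00159), and Srgn, a proteoglycan core protein gene, rose from 46 and 64 to 943 and 898 (4.06 ± 0.27, adjusted p = 0.00469). Pdgfra rose by 5.5 and Foxq1 was at 910 and 434 against 2 and 0. Krt18 and Krt8 led the 3 of 16 trophoblast genes that rose, at 4.01 ± 0.44 (adjusted p = 0.0177) and 4.85 ± 0.62 (adjusted p = 0.0225). Endoderm and trophoblast lists passed by camera (adjusted p = 7.04e-11 and 0.00163; adjusted p = 0.242 with an estimated correlation for both) and by fry (0.00528 and 0.00809). Without the library labelled 2TS22C replicate 2, Gata6 was at 6.9 (adjusted p = 0.0115), the endoderm list at 2.61 (adjusted p = 1.38e-08) and the trophoblast list at 0.84 (adjusted p = 0.00368, from 1.27 with it).

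Sox2 fell 29.3-fold in E57D cells relative to 2TS22C (-4.87 ± 0.47, limma adjusted p = 0.0118) and was at -4.51 without the library labelled 2TS22C replicate 2 (adjusted p = 0.0466). Of 20 naive genes 1 rose and 3 fell, with a median of -0.21 and a camera adjusted p of 0.547. Pecam1 was lower at -1.29 (adjusted p = 0.0108), Esrrb at -0.75 (adjusted p = 0.0309) and Nr5a2 at -1.34 (adjusted p = 0.0441), and Klf4, a Krüppel-like pluripotency factor, rose by 1.48 (adjusted p = 0.0486). Without the library labelled 2TS22C replicate 2, Pecam1 stayed past the test (adjusted p = 0.024) and Esrrb, Nr5a2 and Klf4 did not (0.0652, 0.125 and 0.109). Of 18 general pluripotency genes, Jarid2, a Polycomb cofactor, rose by 1.02 (adjusted p = 0.0449) and Fgf4 fell by 1.35 (adjusted p = 0.034), and both missed the test without that library (0.0786 and 0.0696). For that list the median was 0.2 and the mean -0.01, with a camera adjusted p of 0.535. Pou5f1 was at 0.46 (adjusted p = 0.0834) and Nanog at 0.31 (adjusted p = 0.531).

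Glycolysis and hypoxia genes fell in E57D cells relative to 2TS22C, with 6 of 26 past the test, 13 adjusted over the list alone and a median of -0.68. Ldha fell 3.4-fold (-1.76 ± 0.19, limma adjusted p = 0.0173), with Pgk1 at -1.63 and Pkm at -1.18. Cholesterol synthesis genes were higher with a median of 0.73 and 2 of 23 past the test, Sc5d and Hsd17b7, enzymes of the pathway, at 1 and 1.45; 14 rose and 1 fell adjusted over the list alone. Camera gave adjusted p of 1.44e-06 for glycolysis and 4.14e-05 for cholesterol (adjusted p = 0.398 and 0.696 with an estimated correlation), and fry 0.0147 and 0.113. Mitochondrial genome oxidative phosphorylation genes (2 of 13 rose, mt-Nd4l and mt-Nd6) and 2-cell-like genes (0 of 13) were higher and p53 targets (2 of 20 fell, Ei24 and Zmat3) lower by camera, with adjusted p of 0.0214, 0.0156 and 0.0207 (adjusted p = 0.398, 0.636 and 0.748 with an estimated correlation), and with fry adjusted p of 0.0092, 0.113 and 0.36. Without the library labelled 2TS22C replicate 2, Ldha was at -1.47 (adjusted p = 0.0195), and the glycolysis, cholesterol, 2-cell-like and p53 lists passed (1.83e-06, 1.77e-07, 0.017 and 6.96e-05), while the mitochondrial list did not (0.0549). Of the other genes named here, Pgk1, Pkm, Sc5d, Hsd17b7 and Zmat3 missed the test without that library (0.0511, 0.0585, 0.0801, 0.0532 and 0.108), so that neither cholesterol gene passed. Without 2TS22C replicate 1, the cholesterol list was at 0.44 (adjusted p = 0.0164), the p53 list at -0.01 (adjusted p = 0.686) and the mitochondrial list at an adjusted p of 0.0587, and without E57D replicate 1 the 2-cell-like, p53 and mitochondrial calls ended (0.153, 0.0627 and 0.0516). The p53 call also ended without E57D replicate 2 (0.0523) and, with the 2-cell-like call, outside the lowest 3 GC classes (0.245 and 0.46). The cell cycle list was lower by fry (adjusted p = 0.0102) and not by camera (0.142). By camera, neuroectoderm genes were added on the lower side without the library labelled 2TS22C replicate 2 (0.0477), and endoplasmic reticulum chaperones without 2TS22C replicate 1 (0.00038).

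Against 2TS22C, limma called 703 genes in E57D cells, 383 higher and 320 lower, with 4054 at an unadjusted p under 0.05. The count was 272 without the library labelled 2TS22C replicate 2 (141 higher, 131 lower), 695 without 2TS22C replicate 1 (420 and 275), 295 without E57D replicate 1 (77 and 218) and 63 without E57D replicate 2 (22 and 41). Of the 703, 14.8% lay in the lowest 3 GC classes. Of 63 named genes past the test, 9 passed with each of the 4 libraries left out, among them Sox2, Gata6, Pdgfra, Srgn, Krt18 and Ifitm3. The largest rises included Mgll, which encodes monoacylglycerol lipase (1054 and 960 against 7 and 3), Sox17 (adjusted p = 0.024, or 0.0584 without the library labelled 2TS22C replicate 2), and Mbd3l2, Ubtfl1, Tfec, Elmod1 and Olfr881, at 1 or less in 2TS22C. The largest falls included Trp53i11, a p53-inducible gene (46 and 6 against 625 and 910), Nphs1, which encodes nephrin (5 and 3 against 130 and 256), Pianp, Sema5b, Ftl1 (uncertain for its copy Ftl1-ps1) and the receptors Olfr698, Olfr1277 and Olfr1353. Mgll, Trp53i11, Nphs1, Pianp and Sema5b missed the test without the library labelled 2TS22C replicate 2 (adjusted p = 0.1, 0.108, 0.104, 0.0914 and 0.12).

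SOX2 and E57D cells shared 25 genes changed in the same direction against 2TS22C, 15 higher and 10 lower, and 1 changed in opposite directions. Independent lists of these sizes would share 0.46 higher and 0.51 lower genes, and part of the excess may come from the shared controls. In 100 simulated draws with the same shared 2TS22C libraries and no true difference, too few genes were called to judge the count of 25. The covariance of the log2 fold changes across genes was 0.579, above the simulated mean of 0.366 and highest of 0.412. Their correlation of 0.463 was below the simulated mean of 0.503. The draws gave all groups the same spread per gene, although the 2TS22C libraries differed most within a group (SD 0.518, against 0.462 at most elsewhere). Noisier shared controls raise the covariance by themselves, so its excess cannot be read as a shared change. Genes are not independent replicates, and the shared controls differ from both lines in virus and doxycycline. The shared count was 167 without 2TS22C replicate 1 (129 higher, 38 lower), 24 without the library labelled 2TS22C replicate 2 (17 and 7), 95 without SOX2 replicate 1 (32 and 63), 19 without SOX2 replicate 2 (8 and 11), 17 without E57D replicate 1 (7 and 10) and 11 without E57D replicate 2 (7 and 4).

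2TS22C and mESC differ in line and strain, and the comparison asks how far the parental line stood from wild-type ES cells. Sox2 was at -0.54 ± 0.47 in 2TS22C relative to mESC (limma adjusted p = 1), and at -0.89 without the library labelled 2TS22C replicate 2 (adjusted p = 0.487). Cubn, an endocytic receptor of visceral endoderm, was at 156 and 100 in 2TS22C and at 0 and 1 in mESC (adjusted p = 0.0142). Its adjusted p was 0.041 without the library labelled 2TS22C replicate 2, and the call ended without 2TS22C replicate 1 (0.0987) and without mESC replicate 1 (0.0508). Phex, Cldn1, Olfr836, Lrrtm2 and Gpm6b were higher, all at 1 or less in mESC, and Sis, which encodes sucrase-isomaltase, was at 277 and 364 in mESC and listed at 0 in 2TS22C, a call that ended without 2TS22C replicate 1 (0.0801). Of 7 named genes past the test, 5 passed with each of the 4 libraries left out. Targets of p53 and endoderm genes were higher and cholesterol synthesis genes lower by camera (adjusted p = 9.01e-05, 0.000455 and 0.00506; medians 0.26, 0.54 and -0.2). For all of these the adjusted p was 0.929 with an estimated correlation, and fry called 0 lists (lowest of these 0.959). Without 2TS22C replicate 1, the p53, endoderm and cholesterol calls ended (medians 0.07, 0.06 and 0.01, adjusted p = 0.419, 0.29 and 0.836), and without the library labelled 2TS22C replicate 2 they stayed (medians 0.47, 1.03 and -0.49, adjusted p = 5.7e-05, 0.000294 and 0.000119). LIF-STAT3 genes were added on the higher side without mESC replicate 1 (0.0132). Leaving out the library labelled 2TS22C replicate 2 added general pluripotency, imprinted and LIF-STAT3 genes on the higher side (0.0243, 0.0468 and 0.0243) and endoplasmic reticulum chaperones on the lower (5.7e-05).

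Between 2TS22C and mESC, limma called 27 genes, 24 higher and 3 lower, against 230 at an unadjusted p under 0.05. The count was 100 without the library labelled 2TS22C replicate 2 (80 higher, 20 lower) and 35 without 2TS22C replicate 1 (17 and 18), so the balance toward higher genes depends on 2TS22C replicate 1. Of the 27, 25 lay in the lowest 3 GC classes and 22 were at 2 or less in one group, and limma called 0 outside those GC classes.

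E57D cells were set against mESC, which asks how far cells kept on the variant differ from wild-type ES cells. Sox2 fell by 5.41 on the log2 scale (limma adjusted p = 0.00624), and Cubn rose from 0 and 1 to 1826 and 826 (adjusted p = 0.00122). Foxq1 was at 910 and 434 against 1 and 1, and Gata6 rose by 7.91 ± 0.34 (adjusted p = 0.000825). Ldha fell by 2.05 ± 0.19 (adjusted p = 0.00775). Of 20 naive genes 3 rose and 4 fell. Pecam1 was lower at -1.39 (adjusted p = 0.00617), Esrrb at -0.77 (adjusted p = 0.0245), Nr5a2 at -1.48 (adjusted p = 0.0307), and Klf2, a Krüppel-like factor, at -1.82 (adjusted p = 0.0497), while Klf4, Dppa3, a maternal factor gene, and Tbx3, a T-box factor, rose by 1.64, 1.79 and 1.3 (adjusted p = 0.0347, 0.0428 and 0.0497). Zfp423, a zinc finger factor, and Nphs1 were lower at -6.26 and -6.08. Limma called 1015 genes, 525 higher and 490 lower, with 4406 at an unadjusted p under 0.05. The count was 71 without mESC replicate 1 (54 higher, 17 lower), 61 without mESC replicate 2 (48 and 13), 396 without E57D replicate 1 (129 and 267), 139 without E57D replicate 2 (72 and 67), and 1719 (939 and 780) without the library labelled 2TS22C replicate 2 in the estimate of spread. Of the 1015, 13.8% lay in the lowest 3 GC classes. Of 70 named genes past the test, 8 passed with each library left out, among them Cubn, Gata6, Pdgfra, Srgn and Ifitm3.

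SOX2 cells were set against mESC in the same way. Sox2 was at -2.15 ± 0.47 (limma adjusted p = 0.117). Of the glycolytic genes, Ldha fell to a log2 fold change of -3.06 ± 0.19 (adjusted p = 0.00316), with Pkm at -1.97 (adjusted p = 0.00464), Pgk1 at -2.36 (adjusted p = 0.00912) and Eno1, which encodes enolase, at -1.45 (adjusted p = 0.00818). Slc16a3, which encodes a lactate exporter, fell from 4332 and 4376 to 128 and 21 (adjusted p = 0.0308), and Trh fell by 5.99 (adjusted p = 0.00366). Gata6 rose from 4 and 5 to 34 and 42 (2.82 ± 0.34, adjusted p = 0.0323). Limma called 103 genes, 59 higher and 44 lower, with 3288 at an unadjusted p under 0.05. The count was 47 without mESC replicate 1 (39 higher, 8 lower), 30 without mESC replicate 2 (24 and 6), 226 without SOX2 replicate 1 (88 and 138), 81 without SOX2 replicate 2 (36 and 45), and 773 (477 and 296) without the library labelled 2TS22C replicate 2 in the estimate of spread. Of the 103, 42.7% lay in the lowest 3 GC classes, and of 19 named genes past the test, 7 passed with each library left out, among them Ldha, Trh and Cubn.

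**Figure D4:**
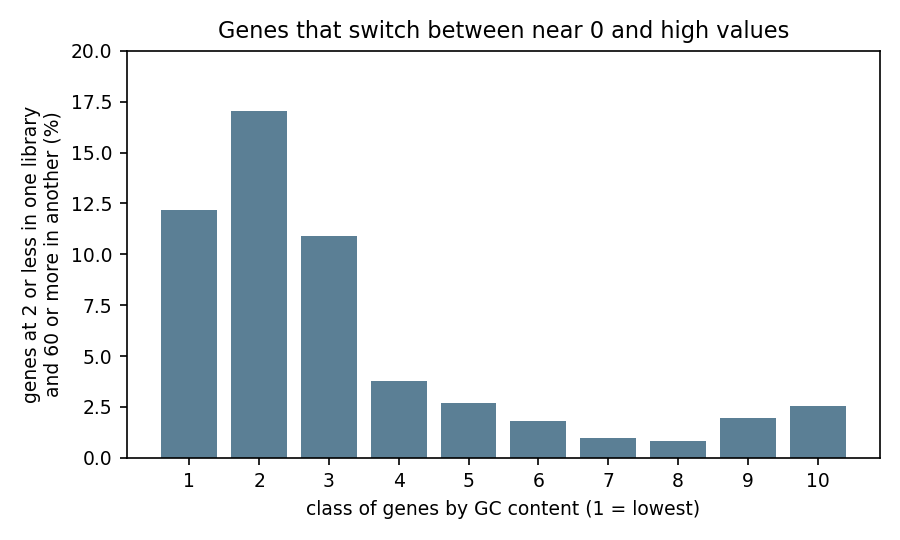
Percent of genes at 2 or less in one library and at 60 or more in another, in each of 10 equal classes of gene GC content (class 1 the lowest), shown as bars from 0. The share was 13.37% over the lowest 3 classes and 2.08% over the other 7.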

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

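Comparisons are in the order E57D against SOX2, SOX2 against 2TS22C, E57D against 2TS22C, 2TS22C against mESC, E57D against mESC and SOX2 against mESC, with 489, 44, 703, 27, 1015 and 103 genes called. Alternatives chosen after seeing the data were a mean of at least 500, leaving out the lowest 3 GC classes, and leaving out the library labelled 2TS22C replicate 2 where it was not compared. A fit of only the 2 groups called 73, 0, 76, 0, 3525 and 755 genes by limma, with the spread estimated from fewer libraries, and the mESC libraries were the closest pair of one group (SD 0.097). With a replicate block the counts were 273, 14, 358, 16, 570 and 56, and 7 genes in the agreement of SOX2 and E57D. The difference between replicates 1 and 2 correlated at 0.133 between SOX2 and E57D and at -0.019 to 0.043 between the other pairs of groups. Pairing by replicate number thus had little support, but a weak pairing of SOX2 and E57D libraries cannot be excluded. With a mean of at least 500, fewer genes were tested and limma called 229, 19, 413, 0, 559 and 45. Without the lowest 3 GC classes, 24 genes (SOX2 against 2TS22C), 0 (2TS22C against mESC) and 57 (SOX2 against mESC) were called, the agreement held 15, and 2 and 4 lists passed for SOX2 and for E57D against 2TS22C, where the mitochondrial list could not be tested because all 13 of its genes lie in those classes. Outside those classes the higher and lower genes were 5 and 19 for SOX2 against 2TS22C (3 and 16 with a mean of at least 500) and 26 and 31 for SOX2 against mESC (15 and 30), and 5 and 10 in the agreement. Without a trend, limma called 73 genes for SOX2 against 2TS22C, 51 for 2TS22C against mESC and 650 for E57D against mESC. Without the library labelled 2TS22C replicate 2, the comparisons that do not include it had 734 (E57D against SOX2), 1719 (E57D against mESC) and 773 (SOX2 against mESC). Leaving out each compared library gave ranges of 93 to 926, 39 to 243, 63 to 695, 26 to 100, 61 to 396 and 30 to 226 genes, and 11 to 167 in the agreement. The ranges for lists were 4 to 8, 4 to 12, 4 to 7 and 0 to 7 in the first 4 comparisons, against 6, 4, 7 and 3; the 12 (5 higher, 7 lower, against 3 and 1) and the last 7 came without the library labelled 2TS22C replicate 2. Camera with an estimated correlation passed 0 lists in each of these 4 comparisons, and fry 5, 3, 5 and 0. The only reversed direction was the cholesterol list in 2TS22C against mESC, at a median of -0.49 without 2TS22C replicate 2 and 0.01 without 2TS22C replicate 1. Where a setting did not test fewer genes or libraries, the cause was not tested. Quantile normalisation, TMM scaling, both pseudocounts and a value of at least 50 left each total of genes within 1.5 times. The higher genes of SOX2 against 2TS22C went from 19 to 12 with quantile normalisation and to 11 at a value of at least 50, and the lower genes of the agreement from 10 to 17 with a pseudocount of 10. TMM scaling ended the 2-cell-like call in SOX2 against 2TS22C (adjusted p = 0.0556), and dropping the filter on low values removed nothing and tests nothing. Depth could not be assessed, because the deposited values carry none.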

Other observations

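The genes of this paragraph, H19, Peg10 against SOX2 cells and the tests of explanations below were chosen after the results were seen, while Peg10 against 2TS22C and the fits with a compared library left out follow rules fixed beforehand. Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis, was at 1978 and 1998 in E57D and at 568 and 746 in SOX2 cells (log2 fold change 1.61 ± 0.16, limma adjusted p = 0.0122), and rose by 1.4 ± 0.16 against 2TS22C (adjusted p = 0.0183, or 0.0451 without the library labelled 2TS22C replicate 2). The call against SOX2 cells ended without E57D replicate 2 (0.0664), and that against 2TS22C without E57D replicate 1 (0.0542) and without E57D replicate 2 (0.0944). Srxn1, which encodes sulfiredoxin, was at 1801 and 1214 in E57D and 186 and 290 in SOX2 cells (2.67 ± 0.44, adjusted p = 0.039), a call that ended without SOX2 replicate 1 (0.138) and without either E57D library (0.123 for both), and it did not pass against 2TS22C (2.15, adjusted p = 0.0533). Txnrd1, Gclc, Slc7a11 and Nqo1, also of glutathione and redox metabolism, had log2 fold changes of 0.66, 0.31, 0.42 and 1.17 between E57D and SOX2 cells and did not pass (adjusted p = 0.0918, 0.349, 0.303 and 0.271). Apart from Slc7a11, a member of the integrated stress response list, these genes were not on a list fixed beforehand. No enrichment of redox genes was tested. Fth1, which encodes the ferritin heavy chain, was at 12894 and 7962 in E57D and 4332 and 5526 in SOX2 cells (adjusted p = 0.0782).

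The imprinted genes Peg10 and H19 had high values in E57D cells. Peg10, a placental gene derived from a retrotransposon, stood at 27115 and 7660 in E57D and between 206 and 999 in the other 6 libraries (log2 fold change 5.08 ± 0.81 against 2TS22C, limma adjusted p = 0.0326, and 4.07 ± 0.81 against SOX2 cells, adjusted p = 0.0598). The Peg10 call against 2TS22C ended without the library labelled 2TS22C replicate 2 (4.04, adjusted p = 0.0786), without E57D replicate 1 (0.0851) and without E57D replicate 2 (0.0797). H19, a non-coding RNA of fetal and extraembryonic tissues, stood at 6985 and 3238 in E57D, 1148 in 2TS22C replicate 1 and 42 or less in the other 5 libraries (adjusted p = 0.0875 for E57D against SOX2).

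The libraries labelled 2TS22C differed from each other by an SD of 0.518, more than the pairs of the other groups, which differed by 0.462 at most. A wrong label on the library labelled 2TS22C replicate 2, or mESC cells in its place, is a candidate explanation, since over 30 genes that set the 5 other engineered-line libraries apart from mESC its median position was -0.008 on a scale with mESC at 0 and those libraries at 1. All 30 genes lay nearer to mESC in that library. Of 108 genes over 2-fold between 2TS22C replicate 1 and the mESC mean, 107 lay nearer to mESC than to 2TS22C replicate 1. A swap with a library of the mESC group was argued against, as the mESC libraries differed by an SD of 0.097 and each lay at 0.488 or 0.498 from 2TS22C replicate 1. Whether mESC cells were also mixed into 2TS22C replicate 1 stays open. Over 6 genes at least 5-fold higher in mESC than in the transduced lines, its median share of the mESC level was 0.204. The shares were 0.12 for Kcnh2, 0.15 for Cavin1, 0.17 for Gm47283, 0.24 for Ftl1 (uncertain for its copy Ftl1-ps1), 0.28 for Hprt and 0.81 for Ndufa4l2. Of the 6 genes, 5 lay from 0.1 to 0.3, but 6 genes are too few to decide. The parental line may also differ from the transduced lines at these genes, which no library here tests.

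Many genes were near 0 in some libraries and high in others, and these were mostly of low GC content. The normalisation within GC classes is a candidate explanation, since among genes with a mean of 50 to 200 the share at 2 or less in one library and 60 or more in another was 25.4% in the lowest 3 GC classes (292 of 1149) and 1.6% in the rest (40 of 2501). Olfactory and vomeronasal receptor genes, silent in most tissues, had a median of 114.5 in those 3 classes over 334 genes. By class, the median was 147.4 in class 1, 43.3 and 20.9 in classes 2 and 3, and 42 in class 4, so the high median rests on class 1. Every gene in the table reached 21 in at least 2 libraries, so receptors below that were not counted. Among low-GC genes, the real grouping of the 2TS22C and mESC libraries gave 33 genes high in one pair and near 0 in the other. The other ways to pair the same 4 libraries gave 34 and 37, so the real grouping had no excess of such genes. This cannot decide whether the line differs from mESC at low-GC genes, because the library labelled 2TS22C replicate 2 resembled mESC. A difference seen in 2TS22C replicate 1 alone would not raise the count of the real grouping. No biological explanation was tested for this pattern.

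In E57D cells endoderm genes were higher and some naive genes lower than in SOX2 cells. Dilution of ES cell transcripts by other cells was set against the general pluripotency genes, whose median was 0.16 with quartiles of -0.35 and 0.62. The naive genes that fell had log2 fold changes from -1.08 to -2.07. They were picked for having fallen, however, while the general list was taken whole. The naive list as a whole had a median of -0.67, and 1 of 18 general genes also fell past the test. The comparison therefore cannot decide whether dilution was the whole cause of the naive falls. Some endoderm-like cells among the E57D cells and a low level of endoderm genes in all E57D cells cannot be told apart in bulk libraries. A single share of such cells would set these genes apart by one factor between the E57D libraries, and the log2 ratio of replicate 1 to replicate 2 had a median of 0.73 and ran from -0.52 to 1.47 over the 9 endoderm genes that rose. An effect of the SOX17 variant itself, SOX17 being a regulator of primitive endoderm, remains open and was not tested, and Sox17 stood at 441 and 92 in the E57D replicates.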
